A study of Danio rerio with 6 samples.

How the data were processed

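Whole zebrafish embryos at 19 hours post fertilization were profiled on an Affymetrix zebrafish expression array. The 6 arrays were 3 of mutant embryos carrying the S6 allele of hand2 and 3 of their phenotypically wild-type siblings. Per the labels' protocols, embryos were kept at 28.5 degrees Celsius, and each array held RNA pooled from 10 to 25 embryos. Per the series' design text, the embryos came from 3 independent crosses, and mutants were told apart by a green fluorescent reporter driven by the heart gene myl7. Sorting on a recessive heart phenotype does not separate homozygous wild-type from heterozygous siblings, so the wild-type group can hold both.

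The deposited values are linear hybridisation intensities, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version and the detection calls are not given in the sources used here. In the values themselves, the mean after trimming 2% from each end lay between 500.107 and 500.133 on all 6 arrays, so each array had been scaled to a common trimmed mean. That scaling fixes the average brightness and leaves differences in the shape of the distribution: the 99th percentile ran from 9409 in mutant replicate 2 to 12771 in wild-type replicate 2. No further scaling was applied for the reported values. Depth has no counterpart on these arrays; their number limits the precision.

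The table held 15617 probe sets. After 115 control probe sets were removed, 15502 remained, and the lowest 25% by mean log2 intensity (below a signal of about 46.09) was left out, which left 11626. The probe set of hand2 was to be kept whatever its level, which mattered only where the lowest 50% was left out. The annotation gave 1 gene symbol to 10795 probe sets, several to 135 and none to 4572. Symbols were updated through gene identifiers to a RefSeq gene table of assembly GRCz12tu, which matched 10711 probe sets. No genome build is named in the sources. The table gave the names, the chromosome and order of the genes, and which lie within 1 Mb of hand2, so results on these rest on that assembly. The tested probe sets named 7356 genes, and the probe set with the highest mean stood for each gene.

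Values were analysed as log2(signal + 16). The offset damps noise near background and understates fold changes of dim genes. With no detection calls, a genotype was taken as at background for a gene where all 3 of its arrays lay at or below the brightest Tag control probe set of the same array. Those maxima ran from 63.7 to 122.3 in siblings and 57.0 to 80.2 in mutants. Such a gene has only a bound, given as at least N-fold: the brighter genotype's mean log2(signal + 16) against the dimmer one's mean of, per array, the higher of its own value and that control. Where an array of the brighter genotype is also at background, its value is taken as read, and the fold given is no strict bound. No fold is given where the bound is not above 1 or both genotypes are at background. This rule, chosen after the results were seen, met 17 of 107 named genes, 2 of them in both genotypes. Genotype was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 2-sided). P-values were adjusted by the Benjamini-Hochberg method over the 11626 probe sets, with an adjusted p under 0.05 as the threshold. Adjusted p-values given for genes below come from this test. Shifts of 22 gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were the alternatives. Within each list, genes were also adjusted over the list alone. Ratios of 3' to 5' control probe sets were compared by an exact permutation test, for which 3 arrays against 3 allow no p below 0.1.

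Named genes followed a rule fixed before the data were examined. It took hand2, the 12 genes higher and 12 lower in the mutant by the largest difference among those past the threshold, the 3 nearest measured genes on each side of hand2, and up to 4 genes of smallest p per list. Because hand2 alone passed, the 12 and 12 were filled with the genes of smallest p in each direction. Separation of the arrays was not asked of them, but in all of them the 3 mutant arrays lay on the same side of the 3 wild-type arrays. Names of the LOC, zgc:, si: and wu: type were passed over, which left out 2.

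The labels number the replicates 1 to 3 in both genotypes without saying that a number marks a cross. Deviations from the genotype means correlated between the 2 arrays of each number at 0.193, 0.119 and 0.482 over the tested probe sets. As every pair exceeded 0.1, the numbers were taken to pair the arrays, on the evidence of the data and not of the labels. That evidence is incomplete. Across genotypes, 4 arrays correlated best with the array of their own number and the others did not, so the pairing stays an assumption. The fit with the number as a replicate block was an alternative. The main fit has no block, so effects shared by a pair stay in its residual and can widen its standard errors. Their median was 0.200, against 0.179 with the block. P-values measure the spread between these pools.

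The fit was tested on simulated data with the real means, spreads already moderated by eBayes, 200 of 11626 probe sets changed, and 3 arrays against 3. It recovered 7.1% of probe sets changed by 0.5 on the log2 scale, 72.6% of those changed by 1, 98.3% at 1.5 and 99.8% at 2. The simulated arrays were independent, so these shares leave out any structure shared between arrays. Moderation draws the spreads of probe sets together, so the shares may be too high for the most variable probe sets. With 200 probe sets changed the adjusted threshold is also easier to reach than with few changed, so the shares are too high for that case.

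Alternatives were the replicate block, quantile normalization, scaling to a common median, offsets of 1 and 64, no intensity filter, the lowest 50% left out, eBayes without the trend, array weights and each array left out in turn. For the counts they also included an adjusted p under 0.1, a minimum change of 1.5-fold and 1 probe set per gene. Added after seeing the data were both arrays of a replicate number left out together, the block with quantile normalization, and the block and each array left out for the comparison of chromosomes and gene order. The planned Fisher's exact test of calls on the chromosome of hand2 was void with hand2 as the only call. Genes at an unadjusted p under 0.05 were used in its place, a choice also made after seeing the data. Figures were drawn with matplotlib 3.10.9.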

Results

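Expression was measured in whole embryos mutant for hand2 (S6 allele), a basic helix-loop-helix transcription factor needed for heart, pharyngeal arch and pectoral fin development, and in their wild-type siblings. Embryos were collected at 19 hours post fertilization, when the heart primordia are assembling. There were 3 arrays per genotype, each of a pool of 10 to 25 embryos. Median signals were between 152 and 177 on the 6 arrays, and log2 signals of any pair of arrays correlated at 0.948 to 0.986 across probe sets. The question set by the design was which transcripts differ between mutants and siblings at this stage.

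The hand2 transcript itself was the clearest difference. Its signal was 362.9 ± 78.7 in wild-type siblings and 49.6 ± 4.0 in mutants (SD, n = 3 each), a fitted log2 difference of -2.51 with a standard error of 0.21 (limma, adjusted p = 0.0051). It was lower in the mutant at all 3 replicate numbers. The mutant signals of 45.1 to 52.8 lay below the brightest of the 17 Tag control probe sets on each mutant array, 57.0 to 80.2, so the remaining signal could not be told from background. The fitted difference is therefore no exact size: it was -2.83 with an offset of 1 and -1.90 with an offset of 64, and against the Tag controls hand2 was at least 4.35-fold lower. The sources used here do not say which part of the gene the allele changes. It missed the threshold without wild-type replicate 1 (log2 difference -2.53, adjusted p = 0.060) or wild-type replicate 2 (-2.36, adjusted p = 0.054).

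**Figure D1:**
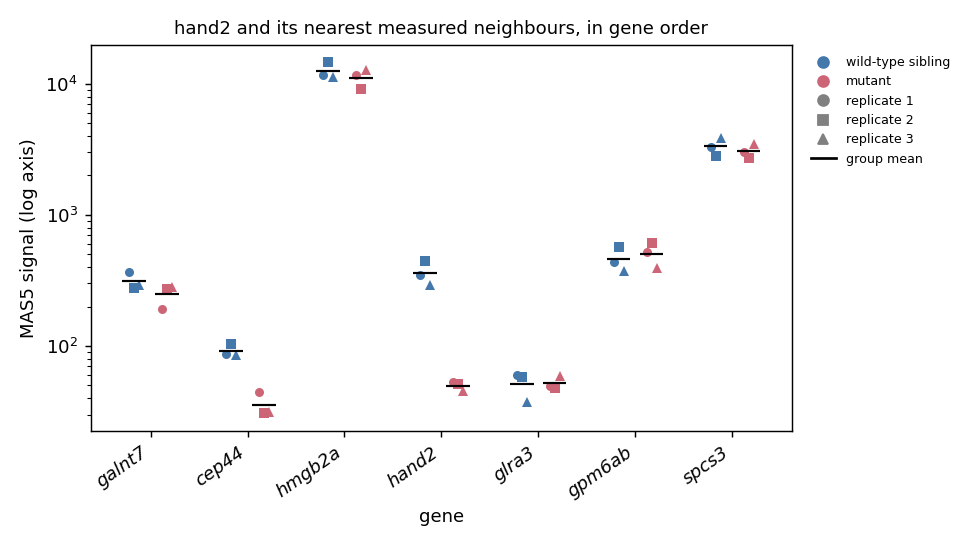
Signal on a logarithmic axis for hand2 and its 6 nearest measured neighbours, ordered as along the chromosome, with 1 point per array (colour for genotype, shape for replicate number) and a bar at each group mean. For hand2 and cep44 the 3 mutant points, all at background, lie below the 3 wild-type points; in the other 5 genes the genotypes overlap.

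Of the genes neighbouring hand2, cep44, which encodes a centrosomal protein, was lower in all 3 mutant arrays. Its signal was 91.9 ± 10.1 in siblings and 35.6 ± 7.9 in mutants (SD, n = 3 each). All 3 mutant arrays and 1 sibling array lay at or below the Tag controls. With that sibling array taken as read cep44 was 1.254-fold lower against the controls. That is no strict bound, and the full size was not measured. It had the smallest p among the genes with lower signal after hand2, 0.00034, and did not pass after adjustment (adjusted p = 0.942, limma). The gene between them, hmgb2a, differed by -0.17 ± 0.17, and galnt7, beyond cep44, by -0.32 ± 0.20. Without mutant replicate 1 galnt7 differed by -0.16, and without wild-type replicate 1 by -0.21. The hmgb2a difference was -0.034 without mutant replicate 2, -0.053 without wild-type replicate 2 and -0.27 without mutant replicate 3. On the other side, gpm6ab and spcs3 differed by 0.13 and -0.11, both less than 1 standard error. Their signs turned with 1 array left out (-0.0022 for gpm6ab without mutant replicate 2, 0.011 for spcs3 without wild-type replicate 3), and glra3 was at background in both genotypes. The 7 measured genes within 1 Mb in the reference gene table did not pass as a set (camera p = 0.076, 0.14 with an estimated correlation, 4 lower and 3 higher), although p was 0.016 without wild-type replicate 3.

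Across the array, hand2 was the only probe set of 11626 past the threshold in limma, and it was the only one with the replicate number as a block. At an unadjusted p under 0.05 there were 352 probe sets, 232 higher and 120 lower in the mutant, against 581 by chance. With the block there were 862, 560 higher and 302 lower. Single arrays moved this share to either side of chance. Of genes on chromosomes other than that of hand2 it was 2.76%, 11.44% without mutant replicate 3 and 1.12% without wild-type replicate 3. The 3 arrays of each genotype did not overlap in 6.75% of probe sets, 431 higher and 354 lower, against the 10% that chance gives for exchangeable arrays. That share leaves out effects common to a replicate number, and the 3 other splits that part all pairs gave 5.505% to 9.195%. The next smallest adjusted p was 0.561. Without mutant replicate 3, 20 probe sets passed, 19 of them higher. In simulated data with 200 probe sets changed, a change of 1 on the log2 scale was recovered for 72.6% and one of 0.5 for 7.1%. With that many changed the adjusted threshold is easier to reach, so these shares do not apply where few probe sets change. In the data, fitted differences of 1.09 for fn1a, 1.19 for cldn3d and -1.34 for myl7 did not pass (limma, adjusted p = 0.942).

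The genes of smallest p with higher signal, none of which passed, included slc12a3, a sodium-chloride cotransporter of kidney tubules, at 47.0 ± 3.3 in siblings and 270.7 ± 184 in mutants. The siblings were at background on all 3 arrays, so it was at least 2.565-fold higher. They also included fn1a, which encodes fibronectin, at 284.9 ± 48.7 and 659.7 ± 268 (1.09 ± 0.30), and cldn3d, a claudin of epithelial tight junctions (1.19 ± 0.31). The kidney genes atp1a1a.4 and hnf1bb and the red cell anion exchanger slc4a1a were in this group too, with hnf1bb and slc4a1a at background in siblings. The others were frem3, smox, sh3bp5la, ubr4 and znf1141, with log2 differences from 0.70 to 0.83, and lrrc15, at background in siblings and given no size. A second frem3 probe set differed by 0.01. With lower signal, after cep44, were dlx5a, an arch and placode homeobox gene (902.4 ± 21.0 and 551.4 ± 85.7, -0.71 ± 0.15), and myl7, the heart myosin light chain gene that drove the sorting reporter (-1.34 ± 0.38). Also lower were rgs12b, gkup, thy1, pax5, dap1b, cdkal1 and ptf1a, between -0.48 and -0.80, and tnfrsfa and gstcd, at background in mutants and given no size. The adjusted p of all these genes was 0.942, and 6 of the genes with higher signal (slc12a3, atp1a1a.4, cldn3d, slc4a1a, fn1a and hnf1bb) passed without mutant replicate 3, with adjusted p from 0.021 to 0.048.

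Genes of the cardiomyocyte contractile list were split. Of 12 measured genes of the contractile list, 7 had lower and 5 higher fitted values, and the list did not pass (camera adjusted p = 0.114; 0.57 with an estimated correlation). Those with the smallest p were myl7 at 310.5 ± 126 in siblings and 113.1 ± 49.2 in mutants, the ventricular myosin heavy chain gene myh7 (137.4 ± 38.8 and 62.4 ± 35.9), cmlc1 (-0.90 ± 0.37) and tnnt2a (-1.01 ± 0.44). None passed after adjustment over the list alone without the block (smallest adjusted p = 0.068, myl7). With the block, 5 passed over the list alone: myl7 (adjusted p = 0.00097), myh7 (0.0061), cmlc1 (0.0061) and tnnt2a (0.010) were lower and nexn (0.026) was higher. Each of the first 4 was lower in the mutant at all 3 numbers, while the siblings of replicate 3 had the lowest signal among the sibling arrays. Without mutant replicate 3 the log2 difference of myh7 was -0.64 (-1.06 with all arrays) and that of tnnt2a -0.45, and without wild-type replicate 1 that of cmlc1 was -0.59. The list passed without mutant replicate 1 (adjusted p = 0.0086), mutant replicate 2 (0.016) or wild-type replicate 3 (0.00094). As written it shares smyd1b with the skeletal muscle list, which was higher. The arrays held whole embryos, and which tissue gave the contractile list's higher genes, such as nexn, was not tested. Mutants were sorted by a reporter driven by myl7, so lower signal of myl7 and other heart muscle genes may be set in part by the sorting. The EGFP control probe set was at background on all arrays, 6.8 to 25.8, and gave no reading of that reporter. Of 11 measured cardiac transcription factors, 9 had higher fitted values, and none passed over the list alone with or without the block; the list reached an adjusted p of 0.115, and 0.024 without mutant replicate 3.

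**Figure D2:**
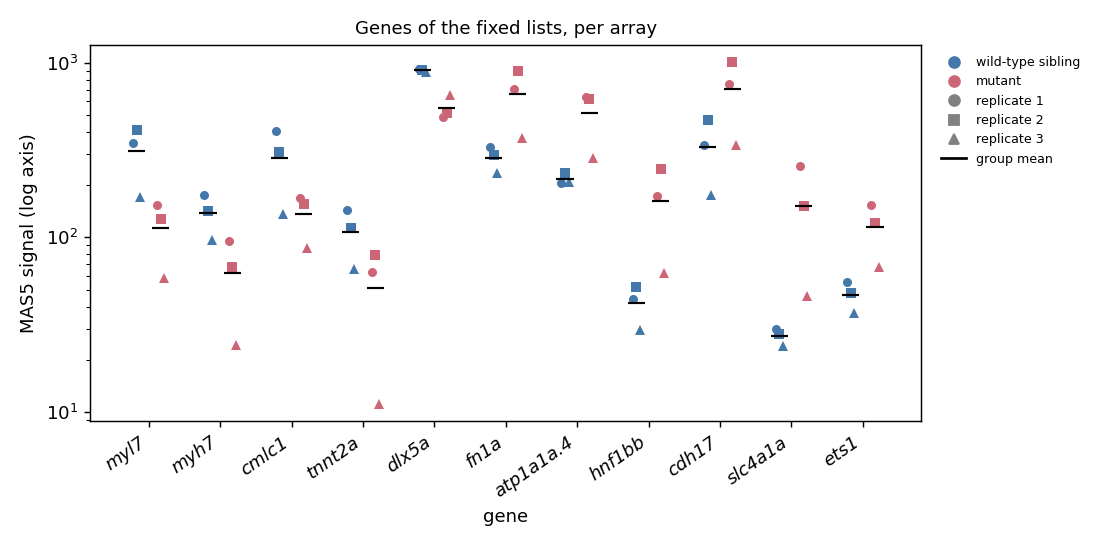
Signal on a logarithmic axis for 11 genes of the fixed lists, with 1 point per array (colour for genotype, shape for replicate number) and a bar at each group mean. The arrays of replicate 3 hold the lowest signal of their genotype in most of these genes, and the mean of myl7 is 310.5 in siblings and 113.1 in mutants.

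Genes of the intermediate mesoderm and pronephros, the embryonic kidney, were shifted upward as a list. Of 14 measured genes, 11 had higher fitted values, with a median log2 difference of 0.17 (camera adjusted p = 0.020; adjusted p = 0.46 with an estimated correlation). The ATPase subunit atp1a1a.4 rose from 215.0 ± 15.7 to 512 ± 197 (limma, adjusted over the list alone, adjusted p = 0.031), and neither it nor hnf1bb passed over all probe sets. The transcription factor gene hnf1bb was at 42.0 ± 11.4 in siblings, at background on all 3 arrays, and 161.1 ± 93.0 in mutants (limma, adjusted over the list alone, adjusted p = 0.031). It was 1.64-fold higher against the Tag controls. This is no strict bound, as mutant replicate 3 was also at background (62.6). With the block, cdh17, a cadherin of the pronephric duct, also passed over the list alone (327.1 ± 148 and 701.9 ± 340, adjusted p = 0.0010; log2 difference 1.04, and 0.66 without wild-type replicate 3), and the list passed by fry (adjusted p = 0.044), which it did not without the block (0.517). The list's median was above 0 at all 3 replicate numbers (0.10, 0.17 and 0.24). The camera call was lost without wild-type replicate 1 (adjusted p = 0.073), mutant replicate 1 (0.065) or wild-type replicate 3 (0.095), without both arrays of replicate 1 (0.170), and with the lowest 50% of probe sets left out (0.145). The median was 0.040 without wild-type replicate 3, 0.061 without mutant replicate 2, 0.097 with a common median and 0.12 with the 3 genes at background set to their bound.

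Of the neural crest and pharyngeal arch list, dlx5a fell when adjusted over the list alone (limma, adjusted p = 0.033). With the block foxc1a was also past the threshold (219.9 ± 61.2 and 410.9 ± 175; limma, adjusted over the list alone, adjusted p = 0.032), with a log2 difference of 0.79, and 1.196 without mutant replicate 3. The list as a whole had 17 of 30 measured genes lower and an adjusted p of 0.099, which was 0.0086 without mutant replicate 1. In the extracellular matrix list, 18 of 30 genes had higher fitted values (adjusted p = 0.115; 0.016 without wild-type replicate 3 and 0.017 without mutant replicate 3). Here fn1a passed over the list alone with the block (adjusted p = 0.012, 0.134 without it), and its paralogue fn1b differed by 0.42 ± 0.20, or 0.27 without wild-type replicate 2. The pectoral fin and lateral plate list, which holds hand2, did not pass (9 of 18 higher, camera adjusted p = 0.532); its median of 0.03 and mean of -0.07 differ in sign.

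Several mesodermal lists had higher values in the mutant. All 18 measured endothelial genes had higher fitted values (median 0.36, camera adjusted p = 2.5e-05; adjusted p = 0.46 with an estimated correlation), among them fli1, lmo2, tal1 and ets1 (46.8 ± 9.5, at background in siblings, and 114.0 ± 42.8). Of the blood genes, 20 of 23 were higher (median 0.26, camera adjusted p = 7.8e-06, and 0.46 with an estimated correlation). Among them slc4a1a was at 27.3 ± 3.1 in siblings, at background, and 150.8 ± 105 in mutants. It was 1.47-fold higher against the Tag controls. This is no strict bound, as mutant replicate 3 was also at background (46.2). The embryonic globin hbae3 was at 2139 ± 450 and 4937 ± 2863. At replicate 3 hbae3 was 2249 in siblings and 2086 in mutants, and its log2 difference of 1.03 was 0.60 without mutant replicate 1 and 1.55 without mutant replicate 3. Of the skeletal muscle genes, 29 of 33 were higher (median 0.40, adjusted p = 4.9e-07; adjusted p = 0.46 with an estimated correlation), including neb (at background in siblings), klhl41b, tnni2b.1 and the regulator myod1 (0.49 ± 0.20). Of the notochord and floor plate genes, 14 of 16 were higher (median 0.39, adjusted p = 0.0031; adjusted p = 0.46 with an estimated correlation; 0.282 without mutant replicate 2). None of these genes passed over its list alone without the block; with it 2 endothelial, 2 blood, 6 skeletal muscle and 2 notochord genes did. The endothelial median was above 0 at all 3 numbers (0.43, 0.48 and 0.11), whereas at replicate 3 the medians of skeletal muscle, blood and notochord were -0.01, -0.02 and -0.05. With the lowest 50% of probe sets left out, the endothelial call was lost (adjusted p = 0.107). The medians moved when single arrays were left out. Mutant replicate 1 also had the lowest actc1b 3' to 5' log2 ratio, 2.18 against 3.31 to 3.91 on the other 5 arrays. As written the skeletal muscle list holds actc1b itself, and the gapdh ratio differed by -0.049 between genotypes at replicate 1. Without mutant replicate 1 the median was 0.14 for skeletal muscle, 0.17 for endothelial and 0.17 for notochord genes, and without wild-type replicate 3 it was 0.23, 0.17 and 0.13. Without mutant replicate 2 it was 0.22 for endothelial and 0.14 for notochord genes, and without wild-type replicate 2 it was 0.39 for blood. Without mutant replicate 3 it was 0.62 for skeletal muscle, 0.63 for endothelial, 0.51 for blood and 0.78 for notochord genes. Without both arrays of replicate 1 all 4 calls were lost, with adjusted p of 0.098 for skeletal muscle, 0.075 for endothelial, 0.096 for blood and 0.1001 for notochord; the notochord call was also lost without both arrays of replicate 2 (0.089).

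**Figure D3:**
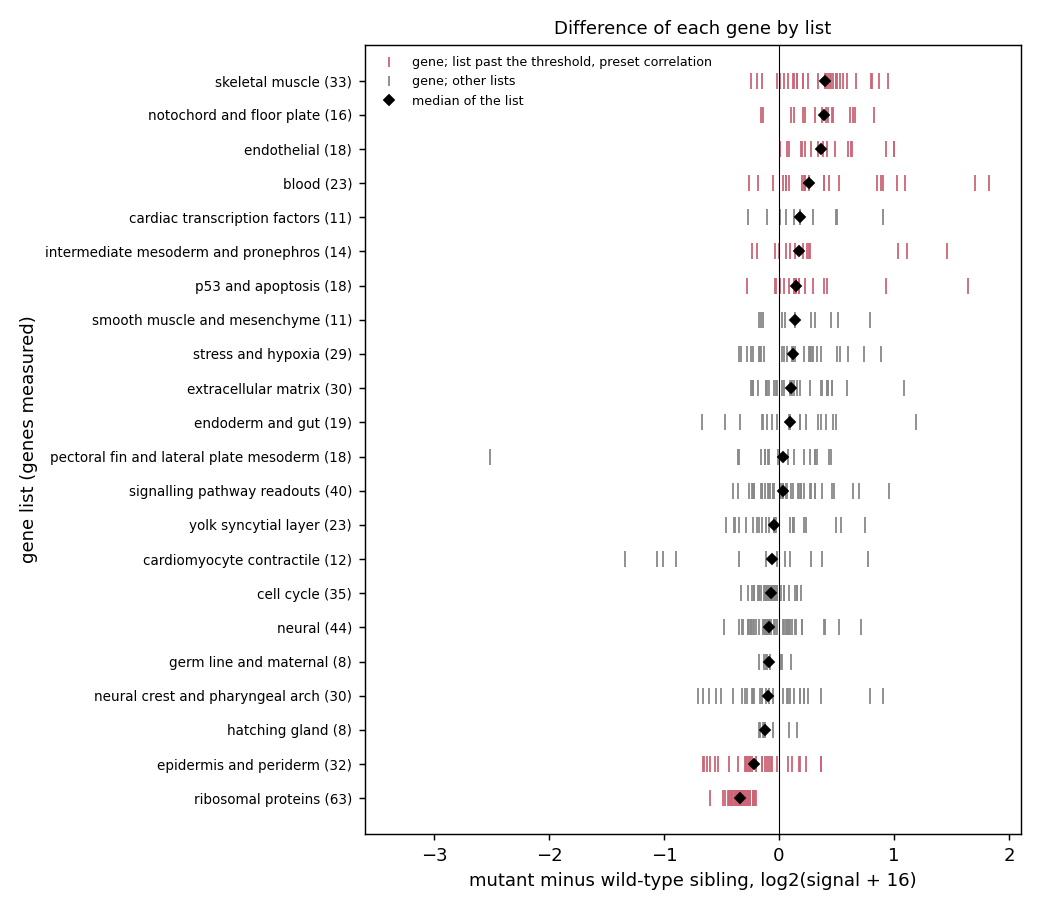
Difference of each measured gene between mutants and wild-type siblings on the log2(signal + 16) scale, grouped by the 22 fixed lists, with a tick per gene and a diamond at the median. Red ticks mark the 8 lists past the threshold with the preset correlation; the ribosomal protein ticks all lie below 0 (their median is -0.003 after quantile normalization), and the isolated tick near -2.5 is hand2.

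Ribosomal protein genes were lower as a list: all 63 measured had lower fitted values, with a median of -0.34 (camera adjusted p = 1.2e-23). The genes moved almost as 1 value, with an estimated correlation of 0.944, and the adjusted p was 0.46 with an estimated correlation. After quantile normalization the median was -0.003 (adjusted p = 0.865) and the shift was no longer seen. The list medians were -0.08, -0.76 and -0.20 at the 3 replicate numbers, and mutant replicate 2 also had the lowest 99th percentile of signal. Without that array the median was -0.22, and without both arrays of replicate 2 it was -0.14. Genes of epidermis and periderm, the surface cell layers, were lower in 25 of 32 (median -0.22, adjusted p = 0.00039; adjusted p = 0.46 with an estimated correlation), with keratin krt17 at 15450 ± 2392 and 10900 ± 3272. Their median was -0.40, -0.28 and 0.04 at the 3 numbers, and the call was lost without mutant replicate 1 (median -0.10, adjusted p = 0.052) or both arrays of replicate 1 (0.210). The median was -0.14 without mutant replicate 2 and -0.13 after quantile normalization.

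The p53 and apoptosis list was higher in 15 of 18 genes (median 0.15, adjusted p = 0.035; adjusted p = 0.46 with an estimated correlation; 0.052 with the block). Its largest differences were in isg15, an interferon-induced gene, and pmaip1, both highest in mutant replicate 2. The siblings were at background for isg15. Without mutant replicate 2 the list's median was 0.053 and its adjusted p 0.627, and the adjusted p was 0.185 without wild-type replicate 1. The call was also lost without both arrays of replicate 1 (0.080) or 2 (0.352), without the intensity filter (0.058), with the lowest 50% left out (0.217) and with array weights (0.111). The median was 0.072 with a common median, 0.098 after quantile normalization and 0.23 without mutant replicate 3. In all, 8 of 22 lists passed with the preset correlation, 6 higher and 2 lower, and 7 with the block. With an estimated correlation or by fry 0 passed, and the smallest adjusted p with an estimated correlation was 0.46. Over the 509 list genes, 4 passed over their list alone without the block and 26 with it, 20 higher and 6 lower.

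The remaining lists did not pass. Of the cell cycle genes, 27 of 35 had lower fitted values (median -0.07, adjusted p = 0.063). The list passed with a common median (median -0.15, adjusted p = 0.034), without mutant replicate 1 (0.049) or mutant replicate 3 (0.024). Its median was -0.013 without mutant replicate 2 (camera adjusted p = 0.756) and -0.033 after quantile normalization (0.491). Smooth muscle and mesenchyme (8 of 11 higher, adjusted p = 0.137) passed without mutant replicate 3 (0.039), as did endoderm and gut (11 of 19 higher, 0.488; 0.033 without that array), where cldn3d passed over the list alone with the block (adjusted p = 0.0045). Of the signalling readouts 23 of 40 were higher (0.232), and the Notch ligand gene dlc passed over the list alone with the block (237.1 ± 135 and 469.8 ± 234, adjusted p = 0.025; log2 difference 0.96, and 0.59 without mutant replicate 1). Stress and hypoxia genes (19 of 29 higher) reached 0.178, and 0.024 after quantile normalization. Their median was 0.12 with all arrays and 0.046 without mutant replicate 2 (camera adjusted p = 0.756). Neural genes (16 of 44 higher, 0.291) and yolk syncytial layer genes (9 of 23 higher, 0.419) passed without wild-type replicate 3 (0.0073 and 0.023). Hatching gland (2 of 8 higher, 0.291) and germ line genes (3 of 8 higher, 0.468) did not pass under any alternative.

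Of the signs of RNA quality, gapdh differed between genotypes by less than the SD within either. For actc1b the difference of -0.42 exceeded the SD of siblings and not that of mutants, where replicate 1 lay apart. The log2 ratio of 3' to 5' control signal was 3.59 ± 0.25 in siblings and 3.17 ± 0.89 in mutants for actc1b, and 1.92 ± 0.13 and 1.95 ± 0.20 for gapdh (SD, n = 3 each; exact permutation test, 2-sided p = 0.7 for both, the smallest possible being 0.1). The actc1b ratio was 2.18 in mutant replicate 1 and 3.31 to 3.91 on the other 5 arrays. The skeletal muscle list as written holds actc1b, and whether its ratio moves with its expression was not tested.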

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

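Leaving out both arrays of a replicate number, and the block with quantile normalization, were chosen after the results were seen, as was the odds ratio for the chromosome of hand2. hand2 stayed lower under every alternative run. It missed the threshold without wild-type replicate 1, without wild-type replicate 2 and without both arrays of any number; with arrays left out, log2 differences ran from -2.65 to -2.36 and adjusted p from 0.018 to 0.396, and fewer arrays leave fewer residual degrees of freedom. It remained the only call under the other settings, and the count ran from 0 to 20 with arrays left out. The replicate block gave 1 probe set and 7 lists, ended the call of the p53 list, and changed no other call of a list by camera or of a named gene over all probe sets; calls over a list alone with it stand in the report. The number of lists past the threshold was 0 with an estimated correlation, 0 by fry, 5 with the lowest 50% left out, and 1 to 15 with arrays left out. The neighbours of hand2 passed by fry (median -0.11) and without the intensity filter (median -0.14), and their median ran from -0.20 to 0.083 with arrays left out. The odds ratio of genes at an unadjusted p under 0.05 on the chromosome of hand2 was 1.66 with the block and 1.23 to 3.90 with arrays left out. By the p adjusted over 25 chromosomes its call was lost with the block (0.108) and, of single arrays, without wild-type replicate 1 (0.128) or mutant replicate 3 (0.759; unadjusted 0.198). Of 1977 values for 106 named genes, 1950 kept their direction and side of the threshold, 9 passed (1 for each of 9 genes, all without mutant replicate 3), and 18 reversed; no gene that reversed had passed. Other reversals were 0.024 for hmgb2a with quantile normalization (with and without the block), -0.033 for glra3 with a common median and -0.015 for org with array weights; glra3 and org were at background in both genotypes, so their signs carry no direction. With arrays left out, values ran from -0.34 to 0.083 for hmgb2a, -0.20 to 0.15 for glra3, -0.0022 to 0.30 for gpm6ab, -0.22 to 0.011 for spcs3, -0.26 to 0.024 for tmed4, -0.17 to 0.31 for org, -0.17 to 0.016 for ddx4 and -0.17 to 2.73 for isg15. For ddx4 and isg15 all 3 sibling arrays and 2 mutant arrays were at background, so their ranges give no exact sizes. No list that had passed changed direction. Camera's direction reversed for the yolk syncytial layer with quantile normalization (median 0.015, with and without the block) and for the fin list with array weights (0.075). With arrays left out, medians ran from -0.22 to 0.028 for the contractile list, -0.090 to 0.064 for the fin list, -0.16 to 0.052 for neural, 0.015 to 0.30 for endoderm, -0.19 to 0.049 for the yolk syncytial layer and -0.18 to -0.016 for germ line genes. The cause was not tested for these, nor for the changes in the number of lists. Signal over background limits the dimmest genes: hand2 in mutants was within the range of the Tag controls, and its log2 difference was -2.83 with an offset of 1 and -1.90 with an offset of 64.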

Other observations

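Mutant replicate 2 stood apart in a number of genes, among them a group of immune genes picked after their values were seen. In that array 64 probe sets were more than 1 log2 unit above every other array, against 0 to 6 in each of the other 5. By the same measure 21 were below every other array, against 0 to 12. The interferon-induced gene isg15 had a signal of 2693 there and at most 61.3 elsewhere, b2m, a subunit of class I antigen-presenting molecules, 3508 against 143.8, and the transcription factor irf1b 1232 against 96.2. The proteasome activator genes psme1 (475.9 against 88.6) and psme2 (910.7 against 160.5), tapbp.1, the chemokine gene ccl19a.1, irg1l, mmp9 and the NF-kappa-B genes nfkbiaa and nfkb2 followed. Genes outside this group stood apart by similar amounts: gnrh2 (1753 against 125.7), spon2b (640.7 against 63.3), tm4sf4, cbln11, uchl1 and rgs4, besides unnamed probe sets. No list of immune genes was tested. The pattern was seen in 1 pool of embryos and was not tested between genotypes.

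In the tests that follow, those of a deletion spanning cep44, of the neighbours without cep44 and of RNA integrity were chosen only after the values were seen. So were the test of a ribosomal fall put into the values, and the block and left-out arrays for the chromosomes and gene order, which moved linked variants from supported to open. Also settled after a first look at the values were keeping a list's own genes out of the random lists it was set against, and asking that RNA integrity and the comparison of chromosomes be judged against their spread, which moved both from argued against to open. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 probe set past the threshold and the highest other split 0 (1 of the 10 splits as large). For the gene lists it gave 8 and the highest other 11, with 4 of the 10 splits as large; of the 3 other splits that part all pairs, the highest also gave 11 lists. The split that set both arrays of replicate 1 and mutant replicate 2 against the rest gave 2411 probe sets at an unadjusted p under 0.05 and 0 after adjustment, which points to a structure of the samples other than genotype.

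The lower ribosomal protein genes may follow brightness-dependent scaling between arrays, and a true fall stays open. Against 10000 random lists of the nearest genes in signal, the median lay at the 37.7th percentile after quantile normalization, which that scaling predicts. As deposited and with a common median it lay below all of them, which decides nothing, since the random lists were dimmer (mean log2 signal 13.69 against 14.24 as deposited; 62 of the 100 brightest genes are ribosomal) and were lower too (median -0.23 as deposited). A fall of -0.34 put into the ribosomal genes alone, alike on all mutant arrays, kept a median of -0.19 after quantile normalization, below all random lists. So the test could have shown a fall of that size confined to these genes. As deposited they lay at -0.34 against -0.23 for the random lists, and a fall as small as that gap was not put in. A true fall shared by other bright genes was not tested, nor was any biological explanation. RNA integrity stays open: the actc1b 3' to 5' ratio differed by 0.14 in replicate 2, where the list was lowest, and by -1.13 in replicate 1, where it hardly moved, but single arrays give no spread for these differences.

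The higher pronephros list may reflect genotype, scaling or stage, and the tests leave each open. After quantile normalization its median was 0.12, at the 98.35th percentile of random lists matched on signal, between the bounds of 95 and 99 set beforehand. Pools of different age would move other maturing tissues as well; in replicate 3 the pronephros median was 0.24 ± 0.11 (SE over genes) while skeletal muscle was at -0.011 ± 0.055 and blood at -0.022 ± 0.077, which met the bound set against this explanation by less than the spread. A second list of 19 measured kidney genes, written before their values were seen, missed the threshold (camera p = 0.072, 13 higher and 6 lower, median 0.16; p = 0.21 with an estimated correlation). That was the outcome set against the idea that other kidney genes are higher too, though a p that misses the threshold does not show that they did not differ. The second list's medians were 0.21, 0.23 and 0.006 at replicates 1 to 3. At replicate 3 it hardly moved, as with skeletal muscle and blood, so stage stays open for these genes too.

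Genes on the chromosome of hand2 were more often at small p, 24 of 349 (6.88%) at an unadjusted p under 0.05 against 193 of 6983 elsewhere (2.76%; Fisher's exact test, 2-sided p = 0.00011; adjusted over 25 chromosomes 0.0028), 11 higher and 13 lower. With the replicate block the adjusted call was lost (11.46% against 7.22%, odds ratio 1.66 in place of 2.60, adjusted p = 0.108), 2 other chromosomes were as high, and it was also lost without wild-type replicate 1 (odds ratio 1.65, adjusted p = 0.128) or mutant replicate 3 (1.23, 0.759), while the odds ratio was 3.90 without wild-type replicate 2. If the gene order of the reference holds, a deletion spanning hand2 and cep44 is argued against by hmgb2a between them, at least 123.5 times the brightest Tag control in each mutant array, and the other 6 neighbours as a set missed the threshold, with a camera p-value of 0.628. Variants linked to the locus stay open: the 24 genes lay nearer hand2 in gene order than the rest (mean 300.8 against 392.9 genes, 1-sided permutation p = 0.034), but not detectably with the block (382.4 against 387.1, p = 0.458) or with single arrays left out except mutant replicate 2 (p from 0.052 to 0.504, and 0.045 without that array). Chance stays open too, as the next chromosome reached 5.93% (16 of 270, exact p = 0.742 for the difference) and the 10 splits, of which 1 was as large and the highest other was 1.52, are too few; line differences between siblings were not tested.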
